A study of Homo sapiens with 38 samples.

How the data were processed

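Counts came from the deposited gene table, which the authors call raw counts. Per the submitters' processing notes, reads were assigned to transcripts with kallisto 0.43.0, so the unit is estimated counts. The genome build, the annotation and the way transcripts were summed to genes are not given in the sources used here. Every column of the deposited table held estimated counts multiplied by 1 constant per library, from 0.265 to 6.58, found as the value shared by the largest number of genes at 1 count. Each column was divided by its constant, after which 56.9% to 81.3% of the values up to 20 counts lay within 0.1 of a whole number, and was then rounded. Deposited column totals were 15.1 to 42.9 M, and the totals after division were 2.45 to 65.7 M, a range of 26.8-fold. Of the 43412 gene symbols 27 had been turned into dates, and they stayed in the tests but are never named. Gene positions and types came from GENCODE release 29 by symbol, which placed 29457 symbols at 1 position.

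Genes were tested with edgeR 4.0.16 in R 4.3.3. All 37 libraries entered 1 quasi-likelihood fit of 19 group means with 18 residual degrees of freedom, to which the lone Wnt3a 72 h library adds none (it is assumed to vary like the others), TMM scaling, trended dispersions (0.00921 to 0.246) and robust estimation. The filter filterByExpr by group left 24304 genes. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called below 0.05. They measure the spread between these libraries, since the labels say only that replicates are biological. Differences between arms were tested as the change in 1 arm from its own 0 h minus the change in the other. These tests, the lists, the comparisons and the rule for naming genes were set before the data were examined. The first fit used 1 dispersion for all genes and was replaced after its calls had been seen, because on simulated counts 28.6% of its calls at Wnt3a 8 h were false, against 9% with trended dispersions. Unchanged simulated genes had unadjusted p below 0.05 in 7.64% and 4.39% of cases.

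The pipeline was tested on simulated data whose dispersions were estimated from the same libraries. With trended dispersions, of 100 genes changed 2-fold and 100 changed 4-fold, 59 and 90 were recovered at CHIR 24 h with 7 unchanged genes called, 60 and 91 at Wnt3a 8 h with 15, 44 and 80 at Wnt3a 72 h with 3, and 37 and 77 for CHIR against Wnt3a at 24 h with 5. With no simulated change at bcat 48 h 0 genes were called. A simulated list of 30 changed members was called, and 0 of 20 unchanged lists were. Genes were simulated independently, so this does not show how the list test behaves when members are correlated.

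The 26 gene lists held 527 members, of which 479 were tested. They were WNT feedback and direct targets, WNT ligands, primed pluripotency, primitive streak and mesendoderm, definitive endoderm, presomitic and somitic mesoderm, lateral and cardiac mesoderm, endothelial and blood, neural ectoderm, neural crest, amnion and trophoblast, HOX genes, epithelial junction, mesenchymal and EMT, BMP targets, NODAL-ACTIVIN targets, FGF-ERK feedback, NOTCH targets, cholesterol synthesis, amino acid and ATF4 response, p53 targets, G2-M and mitosis, S phase, hypoxia and glycolysis, interferon response and mitochondrially encoded mRNAs. Each was tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and comparisons of 1 family, and also with an estimated correlation. Members were counted when called over all genes and when adjusted over the list alone.

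Named genes were chosen by a fixed rule: in each arm at 8, 24 and 72 h (and 120 h for Wnt3a), and between arms at 24 and 72 h, the 4 genes per direction with the largest log2 change among those with adjusted p below 0.05, a mean of at least 5 CPM in the higher group, and both treated libraries on the same side of both 0 h libraries. Clone names and RNA genes were passed over, 1 sex-linked transcript picked by the rule is not reported, 3 other genes are not reported here, and CTNNB1 was named in every arm. From the lists, members with large changes were given, and these, AXIN2, MSGN1, NANOG, POU5F1, SOX17 at CHIR 72 h, NODAL, TOP2A, VWF and FOXD3 were picked after their values had been seen, as were PEG3 and TSPYL5. Log2 changes are fitted values. Their errors can be too small at low counts, where leaving 1 library out moved some changes by more. Where a group had 0 counts the fold is a bound with 3 counts in place of 0 over that group, and where it had 1 to 3 counts the ratio stands with an interval at 95% confidence. Bounds and intervals cover counting error only. Fitted log2 changes and differences at 0 counts in a group, also with 1 library left out, depend on edgeR's default prior count. Such values are given without a bound and are not measured folds. Members of the MT1 family and the pseudogenes RPL23AP42 and ECEL1P1 share sequence with relatives, so the assignment of their reads is uncertain. Scaling was also done with DESeq2 1.42.0. Principal components came from the 2000 most variable genes, and tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and data.table (version 1.17.8).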

Results

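Total RNA was sequenced from H9 cells, an established human embryonic stem cell line, after WNT signalling had been switched on in 3 ways. CHIR99021, which blocks the kinase GSK3 and so spares beta-catenin from destruction, was given at 10 µM for 8, 16, 24, 48 or 72 h. Recombinant Wnt3a, a secreted ligand, was given at 240 ng/ml for 8, 24, 48, 72, 96 or 120 h. In the bcat arm, an H9 line carrying an integrated construct, doxycycline at 1 µg/ml switched on a shortened beta-catenin that resists destruction, for 8, 16, 24, 48 or 72 h. Each arm had its own 0 h cultures, and 19 groups of 2 libraries gave 38 libraries. The columns of both Wnt3a 72 h replicates were identical in all 43412 genes and were used as 1 library, so 37 libraries were compared and that group had n = 1. Depth ran from 2.45 M estimated counts (Wnt3a 0 h replicate 1) to 65.7 M (Wnt3a 0 h replicate 2), with a median of 18.99 M. In the bcat arm 34.1% of the counts of 0 h replicate 1, 60.4% of 24 h replicate 1 and 60.3% of 48 h replicate 2 were cytosolic ribosomal RNA, against a median of 5.14% over all libraries. The 4 libraries in doubt were these 3 and Wnt3a 0 h replicate 1. All cultures left mTeSR1 for RPMI1640 with B27 when treatment began and none received the new medium alone, so each change from 0 h joins the treatment, the medium and the elapsed time.

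**Figure D1:**
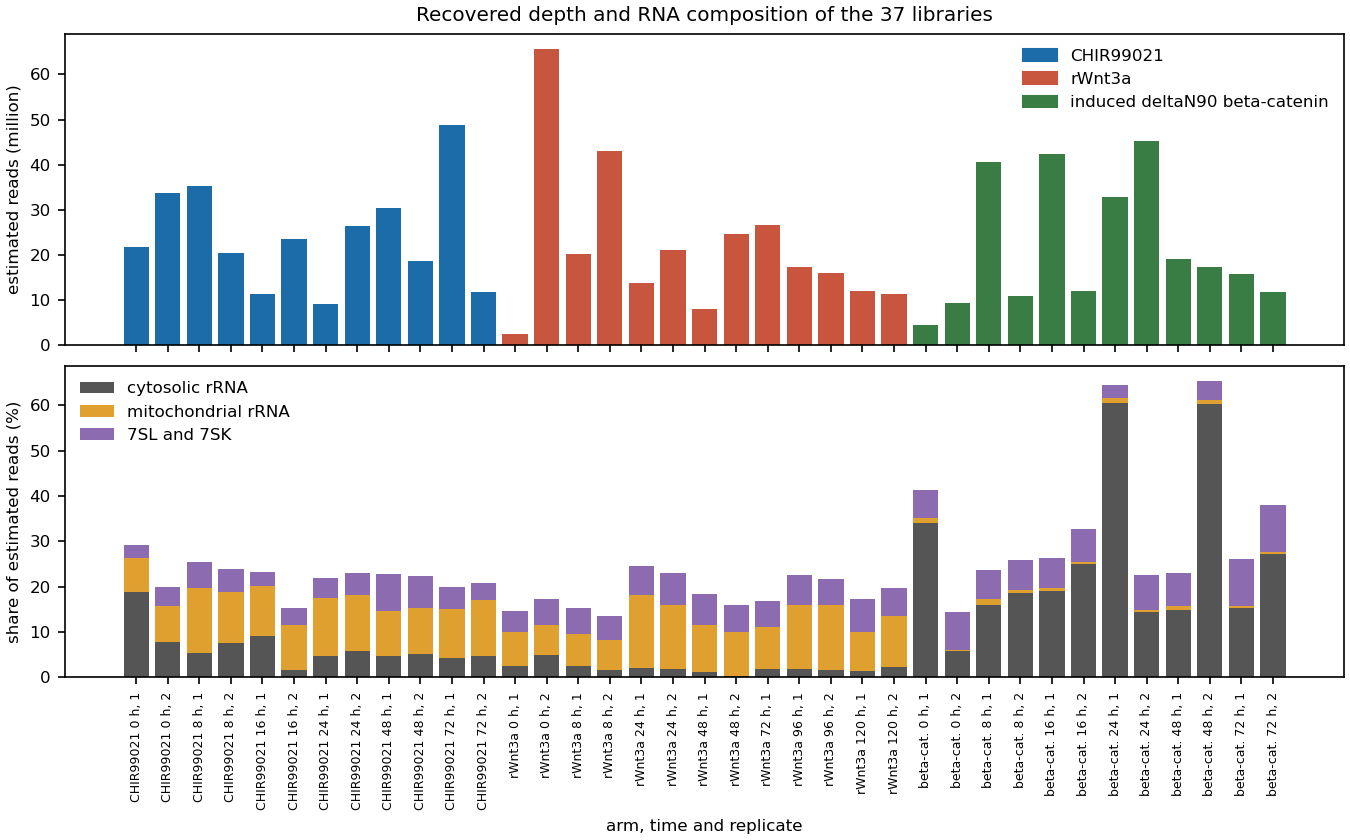
Estimated counts per library in M (upper panel) and the share of them in cytosolic rRNA, mitochondrial rRNA, 7SL and 7SK in percent (lower panel), by arm, hour and replicate. Wnt3a 0 h holds both the shallowest and the deepest library, and cytosolic rRNA reaches its highest shares in the bcat arm.

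CTNNB1, which encodes beta-catenin, rose in the bcat arm by 2.00 ± 0.10, adjusted p = 4.28e-14 at 8 h (log2 ± standard error, n = 2 and 2) and by 1.80 ± 0.10, 1.76 ± 0.10, 1.87 ± 0.10 and 1.68 ± 0.10 at 16, 24, 48 and 72 h. Reads from the induced construct and from the resident gene cannot be separated in gene-level counts. With CHIR99021 CTNNB1 fell at every time, by -0.43 ± 0.10 (adjusted p = 0.00206), -0.61 ± 0.10, -0.85 ± 0.10, -0.96 ± 0.10 and -0.66 ± 0.10 at 8, 16, 24, 48 and 72 h. With Wnt3a it fell at 24 h by -0.49 ± 0.10 (adjusted p = 6.62e-04, but -0.34 and 0.0509 without Wnt3a 0 h replicate 2) and at 96 h by -0.52 ± 0.10 (adjusted p = 1.21e-04). At these hours the median change of lincRNA genes lay furthest above that of protein-coding genes, by 0.53 and 0.704, and by at most 0.376 at other Wnt3a hours. The change of CTNNB1 was not called at 8 h, 0.09 (adjusted p = 0.840), 48 h, 0.04 (adjusted p = 0.862), 72 h, 0.19 (adjusted p = 0.340), or 120 h, -0.13 (adjusted p = 0.377). Over the 2000 most variable genes the first 3 principal components held 27.2%, 22.9% and 12.3% of the variance. The bcat libraries lay apart from both other arms on the second component at all hours, 0 h included, from −56.5 to −38.1, and the other arms lay from 6.42 to 51.5. The first component was 91.6 and 90.4 at CHIR 48 h, 71.6 and 65.3 at CHIR 72 h, and 70.3 and 71.5 at bcat 72 h. The third separated late Wnt3a libraries, at −51.4 and −49.6 at 96 h, from CHIR libraries, at 21.6 to 40.1. Within groups the correlation of replicates across 24304 genes ran from 0.950 (bcat 0 h) to 0.988 (Wnt3a 8 h).

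**Figure D2:**
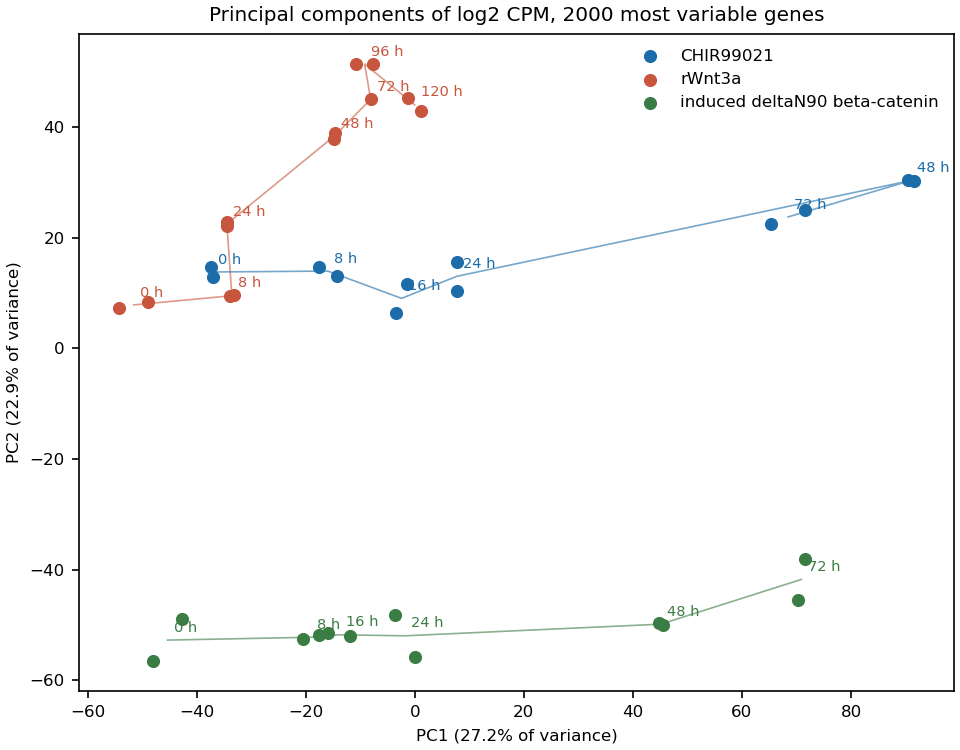
Scores of each library on the first (horizontal) and second (vertical) principal component of the 2000 most variable genes (log2 CPM), coloured by arm, with lines through the group means in order of time. CHIR and Wnt3a part with time, and bcat libraries are apart from the start.

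At 8 h of CHIR99021, SP5, a transcription factor induced by WNT, rose by 8.71 ± 0.39, adjusted p = 1.99e-13, from 0.429 ± 0.104 to 174 ± 12.5 CPM (counts per M counts, mean ± standard deviation, n = 2 and 2). DKK4, a secreted WNT antagonist, had 0 counts at 0 h and was at least 366-fold (adjusted p = 2.55e-11) higher. CDX2, a homeobox factor of the posterior embryo, was at least 161-fold (adjusted p = 3.57e-09) higher from 0 counts. EOMES, a T-box factor of the primitive streak, rose by 7.80 ± 0.59, adjusted p = 6.79e-09, and by 7.01 without CHIR 8 h replicate 1. Among genes of at least 5 CPM the largest falls were those of MIR210HG, host of a hypoxia-induced microRNA (-4.40 ± 0.38, adjusted p = 1.33e-09), and CYP26A1, which degrades retinoic acid (-3.67 ± 0.55, adjusted p = 4.09e-05). STC1, a secreted glycoprotein (-3.49 ± 0.20, adjusted p = 8.82e-14), and HMX2, a homeobox factor (-3.39 ± 0.57, adjusted p = 6.23e-05), followed. Among WNT feedback and direct targets, of 20, 14 rose and 1 fell (14 and 1 adjusted over the list alone), adjusted p = 3.03e-17. MYC was the 1 that fell (-0.91 ± 0.21). Among WNT ligands, of 13, 5 rose (5 adjusted over the list alone), adjusted p = 0.0262 (adjusted p = 0.0573 with an estimated correlation). WNT10B rose by 5.37 ± 0.41 and WNT5B by 4.72 ± 0.19. Among primitive streak and mesendoderm genes, of 22, 10 rose and 0 fell (10 and 1 adjusted over the list alone), adjusted p = 1.07e-04 (adjusted p = 0.0666 with an estimated correlation). In all 5078 genes changed, 2233 higher and 2845 lower. The total was 3210 without CHIR 0 h replicate 2 and 2906 without CHIR 8 h replicate 1. CYP26A1 at 8 h had a log2 change of -4.72 without CHIR 8 h replicate 1. HMX2 at 8 h had a log2 change of -4.11 without CHIR 8 h replicate 2.

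Metabolic and cell cycle lists moved within the same 8 h of CHIR99021 and new medium (n = 2 and 2). Cholesterol synthesis genes also fell at 8 h in the other arms, and hypoxia and glycolysis genes in the bcat arm. Without a culture in the new medium alone, the part of the medium in these falls cannot be separated from that of CHIR99021. Cholesterol synthesis genes fell: of 25, 23 fell (23 adjusted over the list alone), adjusted p = 5e-20. HMGCS1, which encodes an early enzyme of the pathway, fell by -1.75 ± 0.13. Amino acid and ATF4 response genes mostly rose: of 22, 17 rose and 2 fell (17 and 2 adjusted over the list alone), adjusted p = 1.34e-11. SLC7A11, a cystine transporter gene, rose by 4.13 ± 0.20, and DDIT4, an mTOR inhibitor, fell by -2.40 ± 0.29. Hypoxia and glycolysis genes fell, of 20, 15 fell (15 adjusted over the list alone), adjusted p = 5.36e-12. PFKFB4 (-3.00 ± 0.20) and hexokinase HK2 (-2.73 ± 0.17) changed most. Genes of G2-M and mitosis fell too, of 22, 18 fell (20 adjusted over the list alone), adjusted p = 1.1e-14. HMMR fell by -1.45 ± 0.14 and the topoisomerase gene TOP2A by -1.18 ± 0.12. S phase genes were called higher: of 22, 10 rose (11 adjusted over the list alone), adjusted p = 0.00110 (adjusted p = 0.383 with an estimated correlation). So were mitochondrially encoded mRNAs: of 13, 7 rose (10 adjusted over the list alone), adjusted p = 2.42e-05 (adjusted p = 0.324 with an estimated correlation). At 16 h 3863 genes changed, 1593 higher and 2270 lower. The total was 2454 without CHIR 0 h replicate 1, 2198 without CHIR 0 h replicate 2 and 1996 without CHIR 16 h replicate 2. By then p53 targets had fallen, of 20, 10 fell (11 adjusted over the list alone), adjusted p = 2.84e-07. NOTCH targets were called lower, of 13, 3 fell (3 adjusted over the list alone), adjusted p = 0.0318 (adjusted p = 0.302 with an estimated correlation). NOTCH targets at 16 h had adjusted p = 0.0522 without CHIR 0 h replicate 1.

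By 24 h of CHIR99021 posterior homeobox genes had risen from 0 counts: CDX2 was at least 846-fold higher, EVX1 at least 266-fold and CDX1 at least 211-fold (n = 2 and 2). Their adjusted p were 2.12e-12, 2.21e-06 and 4.68e-12. Among genes of at least 5 CPM the largest falls were in NPTX1, a neuronal pentraxin (-6.26 ± 0.77, or -8.06 without CHIR 24 h replicate 2), and SHISA2, which restrains WNT and FGF receptors (-4.68 ± 0.39). DGKK, a diacylglycerol kinase (-4.47 ± 0.20), and NRK, a kinase (-4.04 ± 0.52), followed. WNT feedback and direct targets rose, of 20, 15 rose and 2 fell (15 and 2 adjusted over the list alone), adjusted p = 8.13e-22. SP5 rose by 9.24 ± 0.40 and MYC fell by -2.23 ± 0.23. Primitive streak and mesendoderm genes rose, of 22, 15 rose (17 adjusted over the list alone), adjusted p = 2.33e-19. The ligand gene NODAL rose by 7.04 ± 0.34. Primed pluripotency genes fell, of 22, 1 rose and 15 fell (1 and 15 adjusted over the list alone), adjusted p = 3.21e-11. FOXD3 (-3.85 ± 0.32) and THY1 (-2.62 ± 0.19) changed most. For mesenchymal and EMT genes, of 21, 8 rose and 1 fell (8 and 3 adjusted over the list alone), adjusted p = 2.95e-04. PRRX1, a mesenchymal homeobox factor, rose by 5.95 ± 0.63 and ZEB2, a repressor of E-cadherin, by 4.80 ± 0.26. Epithelial junction genes were called lower: of 20, 1 rose and 10 fell (2 and 12 adjusted over the list alone), adjusted p = 3.69e-04 (adjusted p = 0.233 with an estimated correlation). FGF-ERK feedback genes were called lower, of 17, 1 rose and 8 fell (1 and 10 adjusted over the list alone), adjusted p = 5.34e-04 (adjusted p = 0.211 with an estimated correlation). DUSP6, a phosphatase (-3.43 ± 0.26) changed most. NODAL-ACTIVIN targets were called higher, of 13, 5 rose and 3 fell (5 and 3 adjusted over the list alone), adjusted p = 0.0264 (adjusted p = 0.214 with an estimated correlation). Endothelial and blood, neural ectoderm and interferon response genes were not called (adjusted p = 0.759, 0.226 and 0.822). In all 3525 genes changed, 1433 higher and 2092 lower. The total was 2227 without CHIR 0 h replicate 1, 2147 without CHIR 0 h replicate 2, 2185 without CHIR 24 h replicate 1 and 2178 without CHIR 24 h replicate 2. NODAL-ACTIVIN targets at 24 h had adjusted p = 0.0894 without CHIR 24 h replicate 2 and 0.0525 without the 4 libraries in doubt. FOXD3 at 24 h had a log2 change of -4.60 without CHIR 24 h replicate 2. PRRX1 at 24 h had a log2 change of 7.005 without CHIR 0 h replicate 2.

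At 72 h of CHIR99021 CDX1 was at least 3620-fold, CDX2 at least 3600-fold and EVX1 at least 1170-fold higher from 0 counts (n = 2 and 2). Their adjusted p were 2.66e-17, 1.03e-14 and 2.21e-08. FOXD3, a pluripotency and neural crest factor, fell by -7.66 ± 0.44, adjusted p = 1.42e-14 (-11.74 without CHIR 72 h replicate 1), and its antisense neighbour FOXD3-AS1 by -6.94 ± 0.27. C9orf135, a membrane protein of pluripotent cells, was 268-fold (counting interval 73.7 to 2220, adjusted p = 5.37e-15) lower, and GRIN2B, a glutamate receptor subunit, 203-fold (counting interval 55.9 to 1690, adjusted p = 2.11e-04) lower. HOX genes rose, of 23, 20 rose (20 adjusted over the list alone), adjusted p = 6.65e-33. At 48 h 22 rose (23 adjusted over the list alone). Presomitic and somitic mesoderm genes followed, of 18, 11 rose and 2 fell (12 and 2 adjusted over the list alone), adjusted p = 1.02e-10. MSGN1, a master factor of presomitic mesoderm, had 70.8 ± 13.3 CPM at 48 h and 45.7 ± 15.4 at 72 h. Primed pluripotency genes fell, of 22, 1 rose and 19 fell (1 and 19 adjusted over the list alone), adjusted p = 6.16e-23. NANOG went from 80.1 ± 3.81 CPM to 0.656 ± 0.150 at 48 h and 9.28 ± 2.89 at 72 h. POU5F1 went from 979.9 ± 7.51 to 109 ± 2.05 and 388 ± 17.8. WNT ligands rose, of 13, 8 rose (8 adjusted over the list alone), adjusted p = 2.75e-07. WNT5B rose by 8.55 ± 0.20. Epithelial junction genes fell, of 20, 1 rose and 18 fell (1 and 18 adjusted over the list alone), adjusted p = 2.31e-16. CRB3 fell by -3.45 ± 0.27 and the claudin gene CLDN7 by -3.24 ± 0.17, while the desmosomal DSP rose by 2.33 ± 0.13. The BMP targets rose, of 15, 11 rose and 0 fell (11 and 1 adjusted over the list alone), adjusted p = 4.82e-07. The homeobox gene MSX1 (8.20 ± 0.36) changed most. At 48 h 8231 genes changed, 3825 higher and 4406 lower. At 72 h 6047 genes changed, 2789 higher and 3258 lower, so the libraries labelled 48 h lay further from 0 h than those labelled 72 h. C9orf135 and GRIN2B had log2 changes of -10.56 and -6.15 at 72 h without CHIR 72 h replicate 1.

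Wnt3a had raised SP5 by 8 h, by 9.59 ± 0.56, adjusted p = 4.01e-11 (n = 2 and 2), or by 12.99 without Wnt3a 0 h replicate 2, the deep control library. EOMES rose by 8.66 ± 0.67, adjusted p = 2.92e-08, or 6.08 without it. DKK4, with few counts at 0 h, was 536-fold (counting interval 148 to 4430, adjusted p = 9.24e-10) higher, and T, the brachyury gene of nascent mesoderm, 191-fold (counting interval 52.5 to 1580, adjusted p = 1.73e-11) higher. Among genes of at least 5 CPM the largest falls were those of KCNJ2, a potassium channel (-3.83 ± 0.56), IL21R, a cytokine receptor (-3.52 ± 0.48), NPTX1 (-3.09 ± 0.70) and HESX1, a forebrain homeobox factor (-3.01 ± 0.37). The call of NPTX1 was lost without Wnt3a 8 h replicate 1 (-2.88, adjusted p = 0.125) or replicate 2 (-3.55, adjusted p = 0.108). WNT feedback and direct targets rose, of 20, 11 rose and 1 fell (15 and 1 adjusted over the list alone), adjusted p = 3.03e-17. Primitive streak and mesendoderm genes also rose, of 22, 11 rose (13 adjusted over the list alone), adjusted p = 6.14e-12. NODAL-ACTIVIN targets rose, of 13, 5 rose and 1 fell (8 and 1 adjusted over the list alone), adjusted p = 2.04e-05. NODAL itself rose by 5.01 ± 0.29 and the activin antagonist FST by 4.40 ± 0.20. Cholesterol synthesis genes fell, of 25, 19 fell (22 adjusted over the list alone), adjusted p = 2.69e-41. INSIG1 (-2.29 ± 0.16) and MVK (-2.04 ± 0.18) changed most. In all 839 genes changed, 553 higher and 286 lower. The total was 547 without Wnt3a 0 h replicate 1, 432 without Wnt3a 8 h replicate 1, 482 without Wnt3a 8 h replicate 2, 1593 with adjustment over all comparisons and 549 with the libraries of the arms compared only. DKK4, T and NPTX1 had log2 changes of 11.38, 9.82 and -3.92 at 8 h without Wnt3a 0 h replicate 2. KCNJ2 at 8 h had a log2 change of -4.80 without Wnt3a 8 h replicate 2.

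At 24 h of Wnt3a PDGFB, a growth factor, rose by 6.12 ± 0.52, adjusted p = 5.75e-09 (n = 2 and 2), and SP5 by 7.67 ± 0.61, adjusted p = 4e-09 (without Wnt3a 0 h replicate 2 PDGFB 7.72 and SP5 11.07). EOMES rose by 5.89 ± 0.72, adjusted p = 6.85e-06, and ANKRD1, a target of YAP, by 6.88 ± 0.96, adjusted p = 3.94e-05, but without that library they were not called (3.32, adjusted p = 0.103, and 10.28, adjusted p = 0.110). The metallothionein gene MT1H fell (-3.70 ± 0.24, adjusted p = 1.85e-12), as did IL21R (-3.70 ± 0.50, adjusted p = 3.12e-06) and MAP1A, a microtubule protein gene (-3.65 ± 0.26, adjusted p = 1.21e-11). WNT feedback and direct targets rose, of 20, 12 rose and 2 fell (14 and 2 adjusted over the list alone), adjusted p = 4.06e-05. Yet AXIN2, a negative regulator of the pathway, fell by -0.71 ± 0.21 (adjusted p = 0.0170), from 20.03 ± 2.25 CPM through 62.0 ± 1.46 at 8 h to 12.7 ± 0.0356. That fall was not called without Wnt3a 0 h replicate 2 (-0.54, adjusted p = 0.362), Wnt3a 24 h replicate 1 (-0.70, adjusted p = 0.0765) or Wnt3a 24 h replicate 2 (-0.71, adjusted p = 0.0911). NODAL-ACTIVIN targets rose, of 13, 9 rose and 1 fell (9 and 1 adjusted over the list alone), adjusted p = 2.04e-05. CER1 (4.75 ± 0.37) and LEFTY1 (3.72 ± 0.34) changed most. FGF-ERK feedback genes also rose, of 17, 10 rose and 1 fell (11 and 1 adjusted over the list alone), adjusted p = 1.77e-05 (adjusted p = 0.117 with an estimated correlation). IER3 (3.69 ± 0.31) and EGR1 (2.23 ± 0.36, but 2.25 with adjusted p = 0.0589 without Wnt3a 0 h replicate 2) changed most. The lists at 24 h come from libraries in which lincRNA genes lay 0.53 above protein-coding genes in median change, against -0.057 at 8 h and 0.066 at 48 h. S phase genes fell, of 22, 0 rose and 15 fell (1 and 18 adjusted over the list alone), adjusted p = 7.09e-08 (adjusted p = 0.149 with an estimated correlation). UHRF1 (-1.39 ± 0.18) changed most. Primed pluripotency genes fell, of 22, 11 fell (12 adjusted over the list alone), adjusted p = 5.24e-07. The DNA methyltransferase DNMT3B (-1.84 ± 0.10) changed most. Interferon response genes were called, of 17, 5 rose and 1 fell (5 and 1 adjusted over the list alone), adjusted p = 0.0357 (adjusted p = 0.0668 with an estimated correlation). IFIT1 rose by 2.22 ± 0.33. In all 4913 genes changed, 2263 higher and 2650 lower (1328 and 570 at 2-fold or more). The total was 2447 without Wnt3a 0 h replicate 2, 3214 without Wnt3a 24 h replicate 1 and 2897 without Wnt3a 24 h replicate 2. Interferon response at 24 h had adjusted p = 0.148 without Wnt3a 0 h replicate 2. CER1 and LEFTY1 had log2 changes of 3.95 and 4.53 at 24 h without Wnt3a 0 h replicate 2. AXIN2 at 24 h was not called with the libraries of the arms compared only (-0.70, adjusted p = 0.0511).

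At 72 h of Wnt3a (n = 1 and 2, so errors and p rest on the spread within other groups) FGF17, a ligand of the streak, was 5880-fold (counting interval 1630 to 48500, adjusted p = 1.09e-12) higher from few counts. SOX17, a master factor of endoderm, was 5140-fold (counting interval 922 to 203000, adjusted p = 3.98e-09) higher and GATA6, also an endoderm factor, 1480-fold (counting interval 409 to 12200, adjusted p = 2.79e-11) higher. EOMES rose by 10.44 ± 0.68, adjusted p = 6.02e-10, or 7.87 without Wnt3a 0 h replicate 2. Metallothionein genes, which bind zinc and copper, fell: MT1G at least 332-fold, MT1H 1010-fold (counting interval 181 to 39900, adjusted p = 4.85e-14) and MT1E 721-fold (counting interval 129 to 28500, adjusted p = 1.65e-12). MT1X fell by -7.85 ± 0.44. Definitive endoderm genes rose, of 16, 11 rose and 1 fell (11 and 1 adjusted over the list alone), adjusted p = 4.25e-12. Primitive streak and mesendoderm genes rose, of 22, 21 rose and 0 fell (21 and 1 adjusted over the list alone), adjusted p = 6.52e-29. NODAL-ACTIVIN targets rose, of 13, 7 rose and 0 fell (8 and 1 adjusted over the list alone), adjusted p = 2.38e-06. CER1, a secreted antagonist, rose by 8.93 ± 0.38. Lateral and cardiac mesoderm genes rose, of 19, 10 rose and 0 fell (12 and 1 adjusted over the list alone), adjusted p = 9.36e-05. So did BMP targets, of 15, 12 rose (12 adjusted over the list alone), adjusted p = 1.06e-12. CHRD (4.96 ± 0.69) and MSX1 (4.85 ± 0.56), which were 2.52 and 9.49 without Wnt3a 0 h replicate 2, changed most. NOTCH targets were called, of 13, 6 rose and 2 fell (6 and 2 adjusted over the list alone), adjusted p = 0.0418 (adjusted p = 0.322 with an estimated correlation). Of the 23 HOX genes tested 0 were called, adjusted p = 0.941. At 48 h 3926 genes changed, 1842 higher and 2084 lower (1013 and 1005 at 2-fold or more). The total was 2518 without Wnt3a 0 h replicate 2 and 2601 without Wnt3a 48 h replicate 1. At 72 h 3978 genes changed, 2049 higher and 1929 lower. The total was 2585 without Wnt3a 0 h replicate 2 and 6283 with both identical columns kept. NOTCH targets at 72 h had adjusted p = 0.211 without Wnt3a 0 h replicate 2. FGF17 and CHRD had log2 changes of 13.01 and 5.85 at 72 h without Wnt3a 0 h replicate 1. FGF17, SOX17, GATA6 and CER1 had log2 changes of 8.97, 13.60, 12.80 and 8.13 at 72 h without Wnt3a 0 h replicate 2.

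At 120 h of Wnt3a SOX17 was 8250-fold (counting interval 1480 to 326000, adjusted p = 4.79e-10) higher than at 0 h (n = 2 and 2), at 114 ± 45.2 CPM. GATA3, a factor of amnion and trophoblast, and EVX1 were at least 417-fold and at least 370-fold higher from 0 counts (adjusted p = 5.44e-08 and 2.01e-06). ANKRD1 rose by 12.32 ± 0.83, adjusted p = 9.55e-10 (15.72 without Wnt3a 0 h replicate 2). CUZD1 fell by -7.23 ± 0.39 (-11.93 without Wnt3a 120 h replicate 1) and MT1X by -5.88 ± 0.29. Definitive endoderm genes rose, of 16, 14 rose and 1 fell (14 and 1 adjusted over the list alone), adjusted p = 1.52e-14. Lateral and cardiac mesoderm genes rose, of 19, 14 rose and 1 fell (14 and 1 adjusted over the list alone), adjusted p = 1.5e-09. Every BMP target tested rose, of 15, 15 rose (15 adjusted over the list alone), adjusted p = 2.33e-19. MSX1 (7.68 ± 0.47, or 12.32 without Wnt3a 0 h replicate 2) and MSX2 (7.21 ± 0.43) changed most. Amnion and trophoblast genes were called higher, of 13, 9 rose and 2 fell (9 and 2 adjusted over the list alone), adjusted p = 0.00114. The keratin gene KRT7 (-2.80 ± 0.56) and the GABA receptor gene GABRP (-2.54 ± 0.41) fell. Endothelial and blood genes were called higher, of 15, 5 rose and 1 fell (5 and 1 adjusted over the list alone), adjusted p = 0.0360 (adjusted p = 0.0692 with an estimated correlation). VWF, a clotting factor gene, rose (2.99 ± 0.60, but 1.59 with adjusted p = 0.155 without Wnt3a 0 h replicate 2). Neural crest genes were called higher, of 17, 8 rose and 3 fell (9 and 3 adjusted over the list alone), adjusted p = 0.0264 (adjusted p = 0.139 with an estimated correlation). So were HOX genes, of 23, 6 rose (6 adjusted over the list alone), adjusted p = 0.0169 (adjusted p = 0.195 with an estimated correlation). Primed pluripotency genes fell, of 22, 2 rose and 18 fell (2 and 18 adjusted over the list alone), adjusted p = 2.54e-14. DPPA2 (-3.15 ± 0.43) and TERF1 (-2.76 ± 0.14) changed most. S phase genes were called lower at 120 h, of 22, 2 rose and 10 fell (3 and 13 adjusted over the list alone), adjusted p = 0.0169 (adjusted p = 0.530 with an estimated correlation). At 96 h, when lincRNA genes lay 0.704 above protein-coding genes in median change, S phase genes fell, of 22, 1 rose and 19 fell (1 and 20 adjusted over the list alone), adjusted p = 1.78e-11 (adjusted p = 0.0690 with an estimated correlation). At that hour 9686 genes changed, 4571 higher and 5115 lower (3268 and 2092 at 2-fold or more). The total was 5823 without Wnt3a 0 h replicate 2. At 120 h 6772 genes changed, 2977 higher and 3795 lower (1971 and 1556 at 2-fold or more). The total was 3678 without Wnt3a 0 h replicate 2. With DESeq2 size factors the median of all genes at 96 h moved by 0.104. Endothelial and blood at 120 h had adjusted p = 0.0787 without Wnt3a 0 h replicate 2, 0.0710 without Wnt3a 120 h replicate 1 and 0.0503 with DESeq2 size factors. Neural crest at 120 h had adjusted p = 0.161 without Wnt3a 0 h replicate 2 and 0.0827 without Wnt3a 120 h replicate 1. HOX genes at 120 h had adjusted p = 0.146 without Wnt3a 0 h replicate 2 and 0.0526 without Wnt3a 120 h replicate 2. S phase at 120 h had adjusted p = 0.0833 without Wnt3a 0 h replicate 2 and 0.0687 without Wnt3a 120 h replicate 1. ANKRD1 and MT1X had log2 changes of 11.05 and -7.26 at 120 h without Wnt3a 120 h replicate 1. ANKRD1, CUZD1, MT1X and KRT7 had log2 changes of 12.99, -6.32, -5.23 and -3.44 at 120 h without Wnt3a 120 h replicate 2. SOX17 at 120 h had a log2 change of 14.26 without Wnt3a 0 h replicate 2.

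In the bcat arm ZIC1, a zinc finger factor of neural and somitic tissue, was at least 45.2-fold higher at 8 h, CDX2 at least 34.3-fold and DKK4 at least 25.5-fold, each from 0 counts (n = 2 and 2). Their adjusted p were 1.75e-08, 4.96e-06 and 1.28e-05. GBX2, a homeobox factor of the hindbrain, was 285-fold (counting interval 78.8 to 2350, adjusted p = 1.8e-12) higher. NPTX1 (-4.80 ± 0.57, adjusted p = 4.02e-06) and STC1 (-3.72 ± 0.20, adjusted p = 4.7e-14) fell. So did the ephrin receptor genes EPHA3 (-4.43 ± 0.59, adjusted p = 2.43e-06) and EPHB3 (-3.65 ± 0.45, adjusted p = 5.37e-07). WNT feedback and direct targets rose, of 20, 14 rose (14 adjusted over the list alone), adjusted p = 4.38e-14. SP5 (7.50 ± 0.56, or 13.38 without bcat 0 h replicate 2) was among those that rose. S phase genes rose, of 22, 16 rose and 0 fell (17 and 1 adjusted over the list alone), adjusted p = 3.83e-09 (adjusted p = 0.112 with an estimated correlation). UHRF1 (2.72 ± 0.21) and E2F1 (1.38 ± 0.17) changed most. Hypoxia and glycolysis genes fell, of 20, 0 rose and 16 fell (1 and 16 adjusted over the list alone), adjusted p = 3.81e-13. Cholesterol synthesis genes fell, of 25, 20 fell (22 adjusted over the list alone), adjusted p = 6.99e-19. At 24 h CDX2 was at least 167-fold, EVX1 at least 61.2-fold and HOTAIRM1, a long noncoding RNA, at least 42.5-fold higher from 0 counts. At 24 h, among genes of at least 5 CPM, the largest falls were in NPTX1 (-7.13 ± 0.66), SYT4, a synaptotagmin (-4.66 ± 0.49), IGFBP5 (-4.45 ± 0.28) and EPHA3 (-4.07 ± 0.55). Primed pluripotency genes fell at 24 h, of 22, 2 rose and 13 fell (4 and 16 adjusted over the list alone), adjusted p = 7.66e-09. GDF3 (-2.68 ± 0.40) changed most. NOTCH targets were called lower, of 13, 4 fell (5 adjusted over the list alone), adjusted p = 8.43e-04 (adjusted p = 0.102 with an estimated correlation). At 8 h 4546 genes changed, 2599 higher and 1947 lower. The total was 2961 without bcat 0 h replicate 2. At 16 h 2654 genes changed, 1514 higher and 1140 lower (563 and 599 at 2-fold or more). The total was 1719 without bcat 0 h replicate 1, 1701 without bcat 0 h replicate 2, 1534 without bcat 16 h replicate 1 and 1643 without bcat 16 h replicate 2. At 24 h 3117 genes changed, 1670 higher and 1447 lower. The total was 1929 without bcat 0 h replicate 2, 1896 without bcat 24 h replicate 1 and 1652 without the 4 libraries in doubt. With DESeq2 size factors the split was 1227 higher and 1616 lower at 16 h and 1501 and 2081 at 24 h. GBX2 and EPHB3 had log2 changes of 12.85 and -2.89 at 8 h without bcat 0 h replicate 2. NPTX1 and EPHA3 had log2 changes of -6.43 and -4.85 at 24 h without bcat 24 h replicate 2. EPHA3 at 8 h had a log2 change of -3.84 without bcat 8 h replicate 1. NPTX1 at 24 h had a log2 change of -7.75 without bcat 24 h replicate 1.

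By 72 h of induction CDX2 was at least 945-fold, ZIC1 at least 690-fold and WNT8A, a ligand of the posterior embryo, at least 316-fold higher from 0 counts (n = 2 and 2). Their adjusted p were 6.48e-13, 2.03e-15 and 2.18e-11. NPTX1 fell by -8.29 ± 0.76, CUZD1 by -7.99 ± 0.33, and SCNN1G, an epithelial sodium channel subunit, was 247-fold (counting interval 67.6 to 2050, adjusted p = 5.45e-10) lower. HOX genes rose, of 23, 18 rose (21 adjusted over the list alone), adjusted p = 2.77e-26. Presomitic and somitic mesoderm genes rose, of 18, 12 rose and 1 fell (12 and 2 adjusted over the list alone), adjusted p = 1.27e-08. WNT feedback and direct targets rose, of 20, 17 rose and 1 fell (17 and 1 adjusted over the list alone), adjusted p = 2.16e-14. The antagonist DKK1 rose (9.31 ± 0.52, or 15.50 without bcat 0 h replicate 2), and MYC fell (-1.86 ± 0.27). Primed pluripotency genes fell, of 22, 1 rose and 20 fell (1 and 20 adjusted over the list alone), adjusted p = 2.31e-20. The NODAL coreceptor TDGF1 fell by -5.33 ± 0.22. Epithelial junction genes fell, of 20, 1 rose and 18 fell (1 and 18 adjusted over the list alone), adjusted p = 8.33e-15. DSP was the 1 that rose (2.86 ± 0.13). Mesenchymal and EMT genes rose, of 21, 12 rose and 2 fell (12 and 2 adjusted over the list alone), adjusted p = 3.12e-06. BMP targets rose, of 15, 13 rose and 1 fell (14 and 1 adjusted over the list alone), adjusted p = 3.02e-07. MSX1 (8.72 ± 0.48, or 14.59 without that library) changed most. Neural crest genes were called higher, of 17, 7 rose and 3 fell (7 and 3 adjusted over the list alone), adjusted p = 0.0330 (adjusted p = 0.156 with an estimated correlation). FOXD3 (-4.88 ± 0.55) and ETS1 (-2.99 ± 0.27) fell. S phase genes stood higher at 48 h, of 22, 22 rose (22 adjusted over the list alone), adjusted p = 1.83e-12 (adjusted p = 0.0573 with an estimated correlation). Neural ectoderm genes were called higher at 48 h, of 21, 6 rose and 2 fell (7 and 2 adjusted over the list alone), adjusted p = 0.0236 (adjusted p = 0.325 with an estimated correlation). At 48 h 5172 genes changed, 2709 higher and 2463 lower (1324 and 1474 at 2-fold or more). At 72 h 6632 genes changed, 3316 higher and 3316 lower. Neural crest at 72 h had adjusted p = 0.0865 without bcat 0 h replicate 2 and 0.0557 without bcat 72 h replicate 2. Neural ectoderm at 48 h had adjusted p = 0.0511 without bcat 48 h replicate 2 and 0.0557 without the 4 libraries in doubt. FOXD3 at 72 h had a log2 change of -4.05 without bcat 72 h replicate 1 and -6.06 without bcat 72 h replicate 2.

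**Figure D3:**
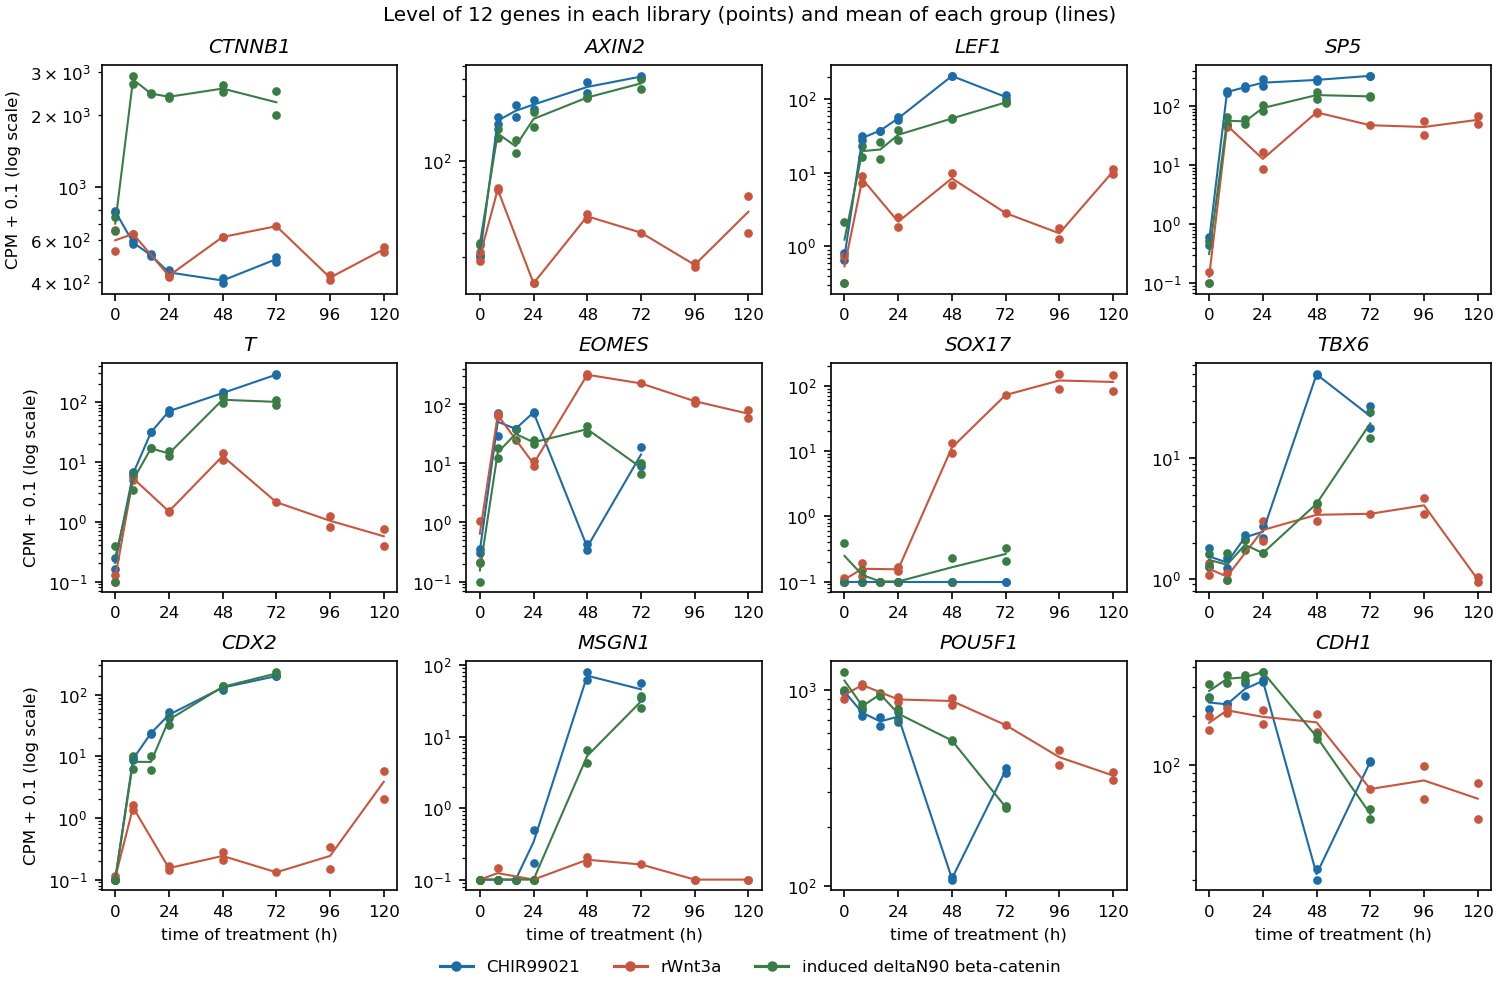
CPM plus 0.1 (vertical, logarithmic) against hours of treatment (horizontal) for 12 genes, with libraries as points and group means as lines. SOX17 climbs in the Wnt3a arm alone, and CDX2 climbs in the other arms.

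**Figure D4:**
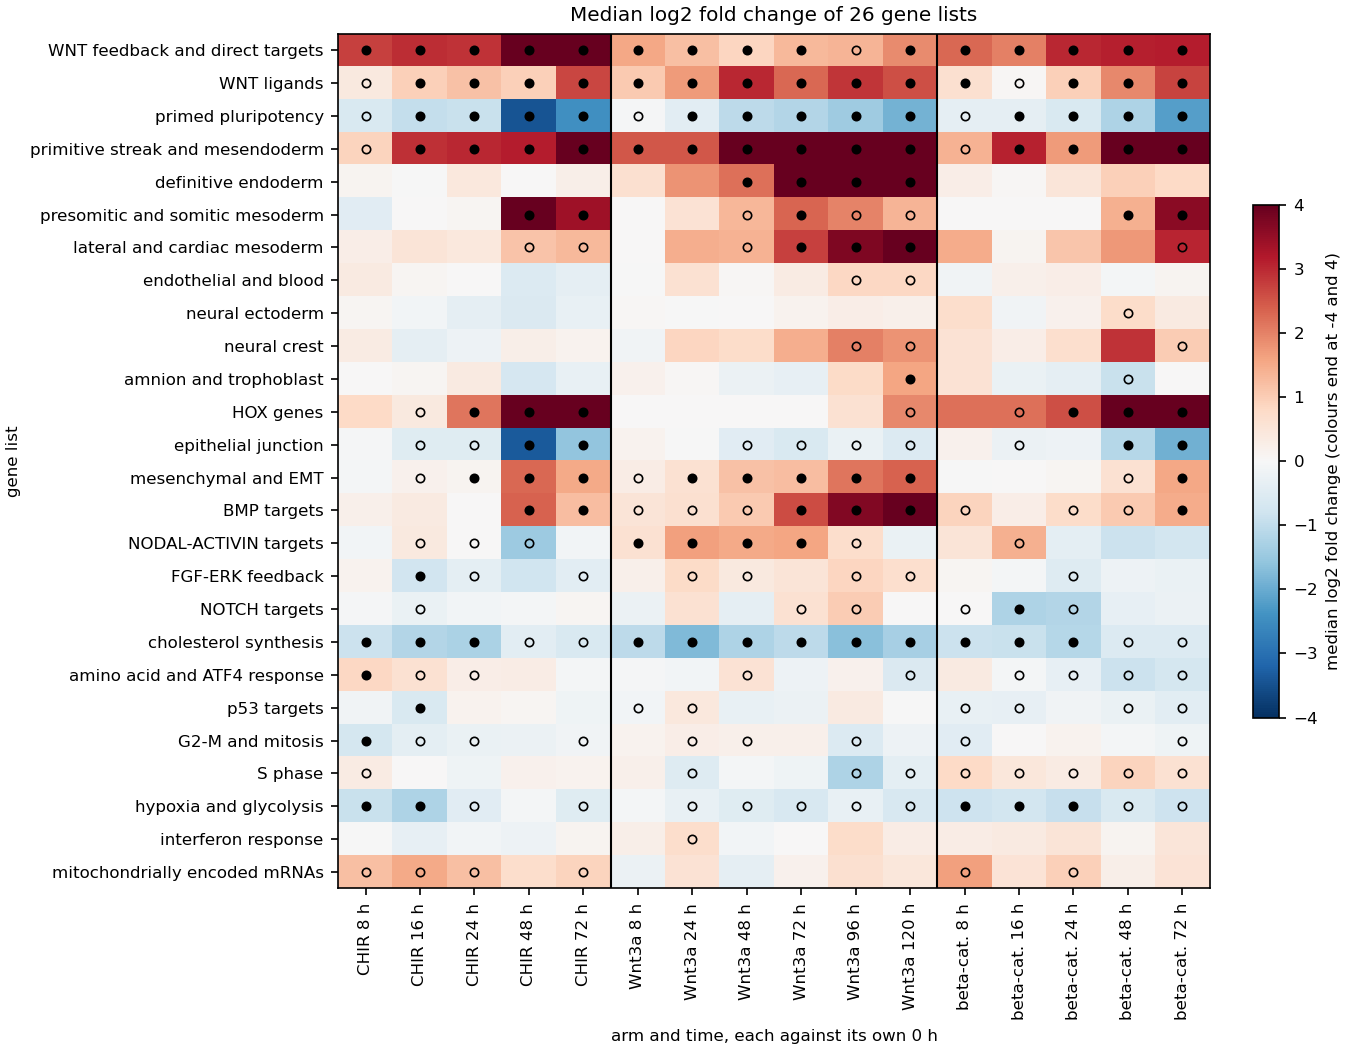
Median log2 change from 0 h (colour) of the members of each gene list (vertical) by arm and hour (horizontal). Filled circles mark lists called with the preset and the estimated correlation, and open circles those called with the preset correlation alone.

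CHIR99021 and Wnt3a, each measured from its own 0 h, were compared at 8, 24 and 72 h (difference of log2 changes ± standard error, n = 2 in all groups but Wnt3a 72 h, with n = 1). The libraries labelled CHIR 72 h lay nearer to 0 h than those labelled 48 h. At 72 h HHEX, an endoderm homeobox factor, differed by -10.87 ± 0.90, LHX1, a factor of the node, by -10.85 ± 1.21, CYP26A1 by -12.21 ± 0.82 and ANKRD1 by -12.63 ± 1.52, all lower with CHIR99021 (adjusted p = 4.11e-10, 1.09e-06, 7.41e-10 and 1.08e-05). Definitive endoderm genes were called lower with CHIR99021, of 16, 4 lower (7 adjusted over the list alone), adjusted p = 1.13e-09: SOX17 had 0 CPM at CHIR 72 h and 72.2 at Wnt3a 72 h. HOX genes were called higher, of 23, 4 higher (5 adjusted over the list alone), adjusted p = 5.56e-40. WNT feedback and direct targets were higher with CHIR99021 at 72 h, of 20, 9 higher and 2 lower (12 and 2 adjusted over the list alone), adjusted p = 1.78e-09, and at 24 h, of 20, 8 higher and 1 lower (11 and 1 adjusted over the list alone), adjusted p = 3.78e-10. In the Wnt3a 24 h libraries lincRNA genes lay 0.53 above protein-coding genes in median change. At 24 h NKD1, a WNT antagonist, differed by 5.82 ± 0.44 and FST by 5.34 ± 0.26, with PDGFB (-8.85 ± 0.72) and GCNT4, a glycosyltransferase (-6.84 ± 0.55), lower (adjusted p = 1.01e-08, 5.79e-14, 8.81e-09 and 1.53e-09). At 8 h ATF4 response genes were called higher with CHIR99021, of 22, 10 higher (14 adjusted over the list alone), adjusted p = 5.01e-15 (adjusted p = 0.0895 with an estimated correlation), and genes of G2-M and mitosis lower, of 22, 16 lower (21 adjusted over the list alone), adjusted p = 2.88e-17 (adjusted p = 0.0895 with an estimated correlation). At 24 h FGF-ERK feedback genes were lower, of 17, 1 higher and 12 lower (1 and 13 adjusted over the list alone), adjusted p = 1.19e-09 (adjusted p = 0.0895 with an estimated correlation). At 8 h 1135 genes differed, 333 higher and 802 lower. The total was 661 without CHIR 0 h replicate 1, 542 without CHIR 0 h replicate 2, 598 without CHIR 8 h replicate 1, 693 without Wnt3a 0 h replicate 1, 641 without Wnt3a 8 h replicate 1, 624 without Wnt3a 8 h replicate 2 and 1888 with the DESeq2 Wald test. At 24 h 2418 genes differed, 1066 higher and 1352 lower. The total was 1572 without Wnt3a 24 h replicate 2. At 72 h 2187 genes differed, 907 higher and 1280 lower. The total was 3287 with both identical columns kept. With DESeq2 size factors the split at 8 h was 570 higher and 672 lower. HHEX and CYP26A1 had log2 differences of -9.51 and -11.51 at 72 h without CHIR 72 h replicate 1. HHEX, LHX1 and ANKRD1 had log2 differences of -14.26, -9.001 and -16.02 at 72 h without Wnt3a 0 h replicate 2. NKD1 and PDGFB had log2 differences of 5.20 and -10.45 at 24 h without Wnt3a 0 h replicate 2. HHEX at 72 h had a log2 difference of -11.83 without CHIR 72 h replicate 2. NKD1 at 24 h had a log2 difference of 6.64 without CHIR 0 h replicate 2.

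CHIR99021 and induced beta-catenin differed in fewer genes (n = 2 in all groups, and the same limit on the CHIR 72 h libraries). DNAJC15, a mitochondrial cochaperone, differed at 72 h by -11.09 ± 0.95 (adjusted p = 6.82e-09): it had 0 counts at bcat 0 h, 29.3 ± 7.68 CPM at bcat 72 h, 12.8 ± 2.29 at CHIR 0 h and 31.5 ± 1.26 at CHIR 72 h. HTR1D, a serotonin receptor, and CPXM2, a carboxypeptidase-like protein, were higher with CHIR99021 at 72 h, by 4.61 ± 0.44 and 4.46 ± 0.41 (adjusted p = 2.74e-08 and 1.84e-08). ZIC1 was lower by -8.44 ± 1.77 (adjusted p = 0.00275, but -8.47 with adjusted p = 0.112 without bcat 0 h replicate 2). At 24 h the chemokine CXCL14 was higher by 4.06 ± 0.49 and EBF3, a neuronal and mesodermal factor, and GBX2 were lower by -6.01 ± 1.12 and -4.21 ± 0.78 (adjusted p = 4.53e-06, 0.00134 and 0.00134). Without bcat 0 h replicate 2 EBF3 and GBX2 differed by -9.95 and -9.12, and EBF3 by -11.50 without CHIR 24 h replicate 2. Amino acid and ATF4 response genes were called higher with CHIR99021 at 8 h, of 22, 8 higher and 0 lower (10 and 1 adjusted over the list alone), adjusted p = 5e-11 (adjusted p = 0.112 with an estimated correlation), and at 24 h, of 22, 10 higher (11 adjusted over the list alone), adjusted p = 1.3e-14 (adjusted p = 0.0895 with an estimated correlation). S phase genes were called lower at 24 h, of 22, 11 lower (15 adjusted over the list alone), adjusted p = 3.66e-07 (adjusted p = 0.292 with an estimated correlation), and neural ectoderm genes lower at 72 h, of 21, 6 lower (8 adjusted over the list alone), adjusted p = 4.47e-06 (adjusted p = 0.120 with an estimated correlation). At 8 h 656 genes differed, 150 higher and 506 lower. The total was 309 without CHIR 0 h replicate 1, 284 without CHIR 0 h replicate 2, 239 without CHIR 8 h replicate 1, 401 without CHIR 8 h replicate 2, 314 without bcat 0 h replicate 1, 323 without bcat 8 h replicate 1, 1073 with the DESeq2 Wald test, 1056 with adjustment over all comparisons and 407 without the 4 libraries in doubt. At 24 h 1202 genes differed, 401 higher and 801 lower. The total was 664 without CHIR 0 h replicate 1, 697 without CHIR 0 h replicate 2, 729 without CHIR 24 h replicate 1, 721 without CHIR 24 h replicate 2, 791 without bcat 0 h replicate 1, 707 without bcat 24 h replicate 1, 782 without bcat 24 h replicate 2 and 597 without the 4 libraries in doubt. At 72 h 1752 genes differed, 779 higher and 973 lower. The total was 1093 without CHIR 0 h replicate 1, 1165 without CHIR 0 h replicate 2, 1167 without CHIR 72 h replicate 1 and 1117 without CHIR 72 h replicate 2. With DESeq2 size factors the split was 271 higher and 349 lower at 8 h and 733 and 583 at 24 h, where the median of all genes moved by 0.108 and 0.118.

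Wnt3a and induced beta-catenin were compared at the same hours (at 72 h n = 1 and 2 against 2 and 2). At 72 h HHEX was higher with Wnt3a by 12.59 ± 0.94, the NODAL antagonist LEFTY1 by 9.82 ± 1.46, CYP26A1 by 8.26 ± 0.89 and LHX1 by 8.10 ± 1.24 (adjusted p = 6.16e-11, 2.2e-05, 9.5e-07 and 7.57e-05). Definitive endoderm genes were called higher with Wnt3a, of 16, 5 higher (5 adjusted over the list alone), adjusted p = 9.52e-10, as were NODAL-ACTIVIN targets, of 13, 9 higher and 1 lower (9 and 1 adjusted over the list alone), adjusted p = 1.38e-07. HOX genes were called lower, of 23, 3 lower (4 adjusted over the list alone), adjusted p = 8.89e-35. Primed pluripotency genes were called higher with Wnt3a, of 22, 10 higher (11 adjusted over the list alone), adjusted p = 6.19e-08 (adjusted p = 0.0895 with an estimated correlation), and WNT feedback and direct targets lower, of 20, 1 higher and 11 lower (2 and 11 adjusted over the list alone), adjusted p = 4.32e-06 (adjusted p = 0.0895 with an estimated correlation). At 24 h CYP26A1 was higher by 6.51 ± 0.90, PDGFB by 5.99 ± 0.71, the phosphatase DUSP8 by 5.64 ± 0.94 and NPTX1 by 5.602 ± 0.93, and ZEB2 was lower by -8.78 ± 0.77 (adjusted p = 3.17e-05, 2.34e-06, 1.44e-04, 2.91e-04 and 8.71e-09). DUSP8 differed by 11.65 without Wnt3a 0 h replicate 2. FGF-ERK feedback genes were higher with Wnt3a at 24 h, of 17, 11 higher (11 adjusted over the list alone), adjusted p = 1.38e-07 (adjusted p = 0.138 with an estimated correlation), and S phase genes lower, of 22, 18 lower (20 adjusted over the list alone), adjusted p = 2.32e-10 (adjusted p = 0.196 with an estimated correlation). In the Wnt3a 24 h libraries on which these rest, lincRNA genes lay 0.53 above protein-coding genes in median change. At 8 h 1361 genes differed, 638 higher and 723 lower. The total was 667 without Wnt3a 8 h replicate 1, 864 without Wnt3a 8 h replicate 2, 840 without bcat 0 h replicate 2, 764 without bcat 8 h replicate 1, 2242 with the DESeq2 Wald test and 773 with the libraries of the arms compared only. At 24 h 3651 genes differed, 1448 higher and 2203 lower. The total was 2417 without Wnt3a 0 h replicate 2 and 2301 without the 4 libraries in doubt. At 72 h 2886 genes differed, 1481 higher and 1405 lower. With DESeq2 size factors the split at 24 h was 2001 higher and 1877 lower, where the median of all genes moved by 0.1. HHEX, LEFTY1 and LHX1 had log2 differences of 15.97, 10.55 and 6.25 at 72 h without Wnt3a 0 h replicate 2. HHEX and LHX1 had log2 differences of 17.22 and 7.19 at 72 h without bcat 72 h replicate 1. They were 11.83 and 9.83 without bcat 72 h replicate 2. PDGFB and NPTX1 had log2 differences of 7.59 and 4.78 at 24 h without Wnt3a 0 h replicate 2. NPTX1 at 24 h had a log2 difference of 6.22 without bcat 24 h replicate 1 and 4.89 without replicate 2. ZEB2 at 24 h had a log2 difference of -12.73 without bcat 0 h replicate 2.

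The arms shared many changes, each arm being compared with its own controls. All arms also shared the new medium and the hours, so sharing beyond independent lists need not reflect WNT signalling. At 72 h 1548 genes were higher and 1858 lower with both CHIR99021 and induced beta-catenin, where independent lists would share 380.5 and 444.5, and 119 went in opposite directions. At 48 h, whose CHIR libraries lay further from 0 h, these were 1274 and 1509 with 431 opposite and a correlation of 0.383. CHIR99021 and Wnt3a shared 900 higher and 1093 lower genes (235.1 and 258.6 for independent lists, 251 opposite). Wnt3a and induced beta-catenin shared 892 and 990 (279.6 and 263.2, 287 opposite). Across genes the correlation of log2 changes at 72 h was 0.498, 0.332 and 0.275 in that order. The weakest match was Wnt3a with induced beta-catenin at 24 h: 345 higher and 412 lower in both (155.5 and 157.8), against 434 opposite (316.8), with a correlation of 0.103, against 0.192 at 8 h and 0.242 at 48 h, and the Wnt3a 24 h libraries stood apart from their neighbours in time, with lincRNA genes 0.53 above protein-coding genes in median change. Among genes changed at least 2-fold in both arms, those sharing a direction at 72 h numbered 1804, 1028 and 1010 for the same pairs, and 281 for the last pair at 24 h. Of the 416 list tests against 0 h 229 were called with the preset correlation and 121 with an estimated correlation, and of the 234 list tests between arms 78 and 7. The 7 were the WNT feedback and direct targets at 24 and 72 h, definitive endoderm and HOX genes at 72 h between CHIR99021 and Wnt3a, and definitive endoderm, HOX and NODAL-ACTIVIN genes at 72 h between Wnt3a and induced beta-catenin.

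The untreated cultures themselves differed between arms. Between the CHIR and Wnt3a arms at 0 h (CHIR against Wnt3a, n = 2 and 2) 2644 genes differed, 1642 higher and 1002 lower. The total was 1411 without CHIR 0 h replicate 1, 1269 without CHIR 0 h replicate 2 and 1681 without Wnt3a 0 h replicate 1. Between the bcat and CHIR arms 3807 genes differed, 1474 higher and 2333 lower (847 and 803 at 2-fold or more). The total was 2403 without CHIR 0 h replicate 1, 2373 without CHIR 0 h replicate 2 and 2521 without bcat 0 h replicate 1. With DESeq2 size factors the splits were 1436 higher and 1356 lower, and 1998 higher and 1955 lower. PEG3, an imprinted zinc finger gene, had 0 counts over both bcat 0 h libraries, where 889 were expected from its level of 69.8 CPM at CHIR 0 h. TSPYL5, a nucleosome assembly protein gene, had 0 counts where 141 were expected. Mitochondrial rRNA made up 0.304% to 1.35% of counts in bcat, 7.52% to 14.3% in CHIR and 6.58% to 16.3% in Wnt3a libraries. Line, arm and any library batch share this split, so the differences between arms were taken from each arm's own 0 h.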

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

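The values here are differences between arms in the change from each arm's own 0 h, at log2 scale for genes, and patterns seen across libraries. Every test of an explanation in this part was chosen after the results had been seen.

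Between CHIR99021 and Wnt3a 1135, 2418 and 2187 genes differed at 8, 24 and 72 h (661 without CHIR 0 h replicate 1, 542 without CHIR 0 h replicate 2, 598 without CHIR 8 h replicate 1, 693 without Wnt3a 0 h replicate 1, 641 without Wnt3a 8 h replicate 1, 624 without Wnt3a 8 h replicate 2 and 1888 with the DESeq2 Wald test at 8 h, 1572 without Wnt3a 24 h replicate 2 at 24 h). At 24 h NKD1 (5.82), LEF1-AS1, antisense to a WNT effector gene (5.47), the streak factor MIXL1 (5.46) and FST (5.34) were higher with CHIR99021. PDGFB (-8.85), ANKRD1 (-8.24), GCNT4 (-6.84) and CYP26A1 (-6.54) were lower. Of these, LEF1-AS1, MIXL1 and ANKRD1 were not called without Wnt3a 0 h replicate 2. LEF1-AS1 then differed by 7.08 (adjusted p = 0.120), ANKRD1 by -11.64 (adjusted p = 0.0870), and MIXL1 turned to -1.23 (adjusted p = 0.982). At 72 h the homeobox genes HOXB2 (13.54), HOXB1 (13.13), HOXA5 (11.78) and NKX6-1 (10.77) were higher, and ANKRD1 (-12.63), CYP26A1 (-12.21), HHEX (-10.87) and LHX1 (-10.85) lower. Without Wnt3a 0 h replicate 2 HOXB2 (10.85), HOXB1 (11.28) and NKX6-1 (7.65) were not called. HOXA5 was not called with any 1 of the CHIR 0 h, CHIR 72 h or Wnt3a 0 h libraries left out. Among lists the adjusted p was 3.78e-10 and 1.78e-09 for WNT feedback and direct targets at 24 and 72 h, 1.13e-09 for definitive endoderm and 5.56e-40 for HOX genes at 72 h. NKD1 and MIXL1 had log2 differences of 6.64 and 6.09 at 24 h without CHIR 0 h replicate 2. NKD1 and PDGFB had log2 differences of 5.20 and -10.45 at 24 h without Wnt3a 0 h replicate 2. HOXB1 and NKX6-1 had log2 differences of 15.23 and 13.68 at 72 h without CHIR 0 h replicate 2. HOXA5, ANKRD1, HHEX and LHX1 had log2 differences of 9.88, -16.02, -14.26 and -9.001 at 72 h without Wnt3a 0 h replicate 2. CYP26A1 and HHEX had log2 differences of -11.51 and -9.51 at 72 h without CHIR 72 h replicate 1. LEF1-AS1 at 24 h had a log2 difference of 6.31 without Wnt3a 24 h replicate 1 and 4.76 without Wnt3a 24 h replicate 2. CYP26A1 at 24 h had a log2 difference of -8.11 without CHIR 24 h replicate 1 and -5.12 without CHIR 24 h replicate 2. NKX6-1 at 72 h had a log2 difference of 10.16 without CHIR 0 h replicate 1. HHEX at 72 h had a log2 difference of -11.83 without CHIR 72 h replicate 2. MIXL1 at 24 h was not called with the values as deposited (4.46, adjusted p = 0.125). HOXB1 at 72 h was not called with the values as deposited (10.78, adjusted p = 1.00). HOXA5 at 72 h was not called with adjustment over all comparisons (11.78, adjusted p = 0.0504), with 1 dispersion for all genes (11.78, adjusted p = 0.0583), with a replicate block (10.73, adjusted p = 0.119) and with the values as deposited (9.69, adjusted p = 1.00). NKX6-1 at 72 h was not called with the values as deposited (10.26, adjusted p = 0.0501).

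Between CHIR99021 and induced beta-catenin 656, 1202 and 1752 genes differed at 8, 24 and 72 h. These counts were lower at every hour with 1 library left out, and at 8 and 24 h without the 4 libraries in doubt. At 8 h the DESeq2 Wald test gave 1073 and adjustment over all comparisons 1056. At 24 h CSMD1, a complement regulator (4.21), GABBR2, a GABA receptor subunit (4.21), CXCL14 (4.06) and the integrin ITGAM (4.005) were higher with CHIR99021. DNAJC15 (-7.38), EBF3 (-6.01), ZEB2 (-4.32) and GBX2 (-4.21) were lower. CSMD1 had adjusted p = 0.0867 without CHIR 0 h replicate 1, 0.0519 without CHIR 0 h replicate 2, 0.0740 without CHIR 24 h replicate 1, 0.108 without bcat 0 h replicate 1, 0.0505 without bcat 24 h replicate 1 and 0.0793 without bcat 24 h replicate 2. DNAJC15 was -7.40 with adjusted p = 0.156 without bcat 0 h replicate 2, and ZEB2 -3.89 with adjusted p = 0.0580 without bcat 0 h replicate 1 and -8.27 with adjusted p = 0.160 without bcat 0 h replicate 2. At 72 h HTR1D (4.61), SCNN1G (4.51) and CPXM2 (4.46) were higher, and DNAJC15 (-11.09), the chromatin gene ASXL3 (-9.86), ZIC1 (-8.44) and the readthrough gene TMEM110-MUSTN1 (-6.30) lower. SCNN1G was 4.24 with adjusted p = 0.0514 without CHIR 0 h replicate 2, 4.28 with adjusted p = 0.327 without CHIR 72 h replicate 1 and 4.25 with adjusted p = 0.0815 without bcat 72 h replicate 1. ASXL3 was -8.39 with adjusted p = 0.217 without CHIR 0 h replicate 1 and -9.88 with adjusted p = 0.150 without bcat 0 h replicate 2, and ZIC1 -8.47 with adjusted p = 0.112 without bcat 0 h replicate 2. CSMD1, EBF3 and GBX2 had log2 differences of 4.91, -9.95 and -9.12 at 24 h without bcat 0 h replicate 2. CSMD1 at 24 h had a log2 difference of 4.83 without CHIR 0 h replicate 2 and 3.53 without bcat 0 h replicate 1. GABBR2 at 24 h had a log2 difference of 3.50 without CHIR 24 h replicate 1, 5.63 without bcat 24 h replicate 1 and 3.27 without bcat 24 h replicate 2. EBF3 at 24 h had a log2 difference of -11.50 without CHIR 24 h replicate 2. ASXL3 at 72 h had a log2 difference of -10.79 without CHIR 0 h replicate 2. CSMD1 at 24 h was not called with no filter on low counts (4.11, adjusted p = 0.0520) and without the 4 libraries in doubt (3.68, adjusted p = 0.0716). DNAJC15 (-7.33) and ZEB2 (-3.58) at 24 h were not called without those 4 libraries. ASXL3 at 72 h was not called with no filter on low counts (-9.76, adjusted p = 0.0670).

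Between Wnt3a and induced beta-catenin 1361, 3651 and 2886 genes differed at 8, 24 and 72 h, and fewer with 1 library left out. At 8 h the DESeq2 Wald test gave 2242 and the libraries of the arms compared only 773. The count at 24 h was lower without the 4 libraries in doubt. At 24 h CYP26A1 (6.51), PDGFB (5.99), DUSP8 (5.64) and NPTX1 (5.602) were higher with Wnt3a, and ZEB2 (-8.78), ZIC1 (-8.62) and DNAJC15 (-8.25) lower. DNAJC15 had 0 counts at bcat 0 h and 11.2 CPM at Wnt3a 0 h, and its difference includes this gap. ZIC1 was not called without Wnt3a 0 h replicate 2, Wnt3a 24 h replicate 2 or either bcat 0 h library. At 72 h HHEX (12.59), LEFTY1 (9.82), CYP26A1 (8.26) and LHX1 (8.10) were higher, and ZIC4 (-14.97), HOXB2 (-14.07) and ZNF831 (-12.54) lower. Without Wnt3a 0 h replicate 2 ZIC4 (-10.89), HOXB2 (-11.38) and ZNF831 (-8.76) were not called. Among lists at 72 h the adjusted p was 9.52e-10 for definitive endoderm, 8.89e-35 for HOX genes and 1.38e-07 for NODAL-ACTIVIN targets. PDGFB, DUSP8, NPTX1 and ZIC1 had log2 differences of 7.59, 11.65, 4.78 and -5.14 at 24 h without Wnt3a 0 h replicate 2. HHEX, LEFTY1 and LHX1 had log2 differences of 15.97, 10.55 and 6.25 at 72 h without Wnt3a 0 h replicate 2. HHEX and LHX1 had log2 differences of 17.22 and 7.19 at 72 h without bcat 72 h replicate 1. They were 11.83 and 9.83 without bcat 72 h replicate 2. NPTX1 at 24 h had a log2 difference of 6.22 without bcat 24 h replicate 1 and 4.89 without replicate 2. ZEB2 at 24 h had a log2 difference of -12.73 without bcat 0 h replicate 2. ZIC1 at 24 h had a log2 difference of -9.87 without Wnt3a 24 h replicate 1 and -7.73 without Wnt3a 24 h replicate 2. ZIC1 at 24 h was not called with the libraries of the arms compared only (-8.56, adjusted p = 0.0638), with the values as deposited (-3.46, adjusted p = 0.386) and without the 4 libraries in doubt (-8.46, adjusted p = 0.0759). ZNF831 at 72 h was not called with the values as deposited (-11.28, adjusted p = 0.0568).

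Libraries labelled CHIR 48 h lay further from 0 h than those labelled 72 h: on the first component of the CHIR arm they scored 93.2 and 91.7 against 57.9 and 49.1, with −17.6 and −18.0 at 24 h. Of the genes called between bcat 48 h and 72 h only 20.7% changed in the same direction between CHIR 48 h and 72 h, where the same count from 24 h to 48 h gave 82.5%, and an exchange of both pairs of labels would produce this, as would cultures that differed in pace. A mixture of cells as at 24 h and 48 h would leave no gene above both. Yet 56 genes were called at least 2-fold higher at 72 h than at both, over the limit of 50 set for this test. They argue against a mixture alone for those genes, but false calls among them were not counted. Depth would not place both 72 h libraries on the same side, since the gap between them was 0.26 of the smallest gap to a 48 h library. Whether the labels were exchanged stays open. If they were, all CHIR values given at 72 h, also those between arms and shared with other arms, would be those of 48 h.

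The Wnt3a 24 h and 96 h libraries stood apart from their neighbours in time: 3225 genes were called at both against their neighbours, and 3160 of them went the same way, where independent calls would leave 685.7 genes called at both in the same direction. Scaling alone cannot account for it, since 37.9% of these 3160 went in the rarer direction. The median of the WNT targets stayed below its neighbours in every setting tried, by −0.214 to −0.352. These settings used only TMM scaling or DESeq2 size factors. RNA composition differed at these hours: lincRNA genes shifted from protein-coding genes by 0.53 and 0.704 (at most 0.376 at other hours, a margin of 0.153). Mitochondrial rRNA was 14.1% to 16.3% of counts, and 6.58% to 11.2% at other hours. A lapse in WNT signalling was not settled. Genes called higher at 24 h in both the CHIR and the bcat arm had a median residual of −0.266 at 24 h (percentile 0 of matched random lists). At 96 h their median residual was −0.081 (percentile 3.62). These genes can include responses to the medium and the elapsed time, so their residuals do not read WNT signalling alone. A handling step at these hours, such as the medium renewal, was not tested.

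A set of 5 genes was near 0 in both bcat 0 h libraries and expressed in both other 0 h groups: AC016739.2, DNAJC15, MSL3P1, PEG3 and TSPYL5. Depth cannot account for it: in the 3 treated CHIR and Wnt3a libraries with fewer effective counts than both bcat 0 h libraries together (12.7 M) each gene had at least 38 counts, against at most 4 over the bcat pair. Loss in library preparation was not settled, as 25% of the 4 genes of known class were histone genes or of other RNA classes (exact interval 0.631% to 80.6%). A difference between the H9 cultures or lines may be the reason, and 3 of the 5 stayed under 0.5 CPM in every bcat library, but line, arm and batch share 1 split here.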

How the results depend on the processing

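The alternatives of this part were chosen before the data were examined, except the values as deposited, the identical columns, the 4 libraries in doubt, the single dispersion and list tests with a library left out, which were chosen after the results had been seen. With 1 library left out, counts of changed genes had these ranges (lowest, highest). They rose only at Wnt3a 8 h and for CHIR−Wnt3a at 8 h, to the highest values there, both without Wnt3a 0 h replicate 2. The cause was not tested beyond the smaller number of libraries: CHIR 8 h 2906 to 3845, CHIR 16 h 1996 to 2735, CHIR 24 h 2147 to 2227, CHIR 48 h 6084 to 6561, CHIR 72 h 4091 to 4616, Wnt3a 8 h 432 to 966, Wnt3a 24 h 2447 to 4426, Wnt3a 48 h 2518 to 3352, Wnt3a 72 h 2585 to 3679, Wnt3a 96 h 5823 to 9086, Wnt3a 120 h 3678 to 6371, bcat 8 h 2961 to 3461, bcat 16 h 1534 to 1719, bcat 24 h 1896 to 2322, bcat 48 h 3695 to 4250, bcat 72 h 4544 to 5593, CHIR−Wnt3a, 8 h 542 to 1574, CHIR−Wnt3a, 24 h 1572 to 2267, CHIR−Wnt3a, 72 h 1583 to 1979, CHIR−bcat, 8 h 239 to 591, CHIR−bcat, 24 h 664 to 1041, CHIR−bcat, 72 h 1093 to 1416, Wnt3a−bcat, 8 h 667 to 1334, Wnt3a−bcat, 24 h 2417 to 3615, Wnt3a−bcat, 72 h 2317 to 2727, 0 h, CHIR−Wnt3a 1269 to 2043, 0 h, bcat−CHIR 2373 to 2603.

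Other alternatives moved a count by over 1.5 times in these cases, and the cause was not tested where none is given. The DESeq2 Wald test gave 1888, 1073 and 2242 differing genes at 8 h for CHIR−Wnt3a, CHIR−bcat and Wnt3a−bcat. Adjustment over all comparisons gave 1593 at Wnt3a 8 h and 1056 for CHIR−bcat at 8 h. Keeping both identical columns gave 6283 at Wnt3a 72 h and 3287 for CHIR−Wnt3a at 72 h, where the copy leaves no spread in that group. The libraries of the arms compared alone gave 549 at Wnt3a 8 h, 773 for Wnt3a−bcat at 8 h and 331 genes shared by Wnt3a and bcat at 8 h. Without the 4 libraries in doubt the counts were 1652 at bcat 24 h, 597 for CHIR−bcat at 24 h, 407 for CHIR−bcat at 8 h and 2301 for Wnt3a−bcat at 24 h. An estimated correlation left 121 list calls against 0 h and 7 between arms. At 2-fold or more, genes sharing a direction at 8, 24, 48 and 72 h numbered 271, 398, 1043 and 1028 for CHIR and Wnt3a, 800, 569, 1486 and 1804 for CHIR and bcat, and 233, 281, 792 and 1010 for Wnt3a and bcat, since fewer genes pass.

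CTNNB1 kept its call under every alternative but 1: at Wnt3a 24 h it was −0.34 without Wnt3a 0 h replicate 2, and the cause was not tested. With 1 library left out its log2 change was CHIR 8 h -0.46 to -0.41, CHIR 16 h -0.62 to -0.60, CHIR 24 h -0.88 to -0.81, CHIR 48 h -0.999 to -0.92, CHIR 72 h -0.70 to -0.63, Wnt3a 8 h -0.05 to 0.24, Wnt3a 24 h -0.63 to -0.34, Wnt3a 48 h -0.09 to 0.20, Wnt3a 72 h 0.06 to 0.35, Wnt3a 96 h -0.66 to -0.37, Wnt3a 120 h -0.26 to 0.03, bcat 8 h 1.90 to 2.10, bcat 16 h 1.71 to 1.91, bcat 24 h 1.66 to 1.86, bcat 48 h 1.77 to 1.98, bcat 72 h 1.51 to 1.84. MIXL1 reversed to −1.23 between CHIR99021 and Wnt3a at 24 h without Wnt3a 0 h replicate 2 (−1.23 to 6.09 with 1 library left out), and the cause was not tested. A replicate block, with the number as covariate within each arm, moved the counts of changed genes by less than 1.5 times, for example to 3422 at CHIR 24 h, 4603 at Wnt3a 24 h and 2972 at bcat 24 h, and gave 228 list calls against 0 h (4 lost and 3 gained) and 75 between arms (3 lost). Under it HOXA5 between CHIR99021 and Wnt3a at 72 h (10.73, adjusted p = 0.119) and RPL23AP42 at Wnt3a 120 h (−9.57, adjusted p = 0.0826) were not called. No strong pairing by number was seen across genes: deviations of same-numbered libraries correlated between −0.052 and 0.055 over 15 pairs of groups in each arm. A weaker pairing, or a pairing in few genes, could be hidden by counting noise and is not excluded. DESeq2 gave no adjusted p for EBF3 and ITGAM between CHIR99021 and bcat at 24 h. Depth limits low genes most in Wnt3a 0 h replicate 1, with 2.45 M counts, and bcat 0 h replicate 1, with 4.44 M.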
